A study of Physcomitrium patens with 10 samples.

How the data were processed

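Small RNAs were sequenced from protonemata, the filamentous juvenile stage, of wild-type moss (Physcomitrium patens, formerly Physcomitrella). Per the labels, the plants were 10 days old and had grown at 25 °C on BCD medium with 50 uM ammonium tartrate and 16 h of light and 8 h of dark per day. Total RNA was isolated with a miRNeasy kit and barcoded libraries were made with the Illumina TruSeq small RNA kit. The labels also name a library made with an earlier Illumina kit, under a name that none of the 10 files carries. All 10 files have a barcode index in the labels, as stated there for the TruSeq libraries only, so all were treated as TruSeq libraries. The labels do not settle whether a library of old batch 1 is the one made with the earlier kit.

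Each deposited file held the distinct read sequences of a sample and, for each, the count of reads with that sequence; a distinct sequence is called a tag below. The labels give the sequence of the 3′ adapter. Sequences in the files ran from 15 to 42 nt, and the counts were whole numbers with totals that differed between samples, which is the unit of raw tag counts that the authors deposited. The trimming tool and its settings are not given in the sources used here, and no aligner was involved in making these files as far as their contents show. Between 66.7% and 73.0% of the tags in a file had a single read. No genome was used here, so tags were not placed on chromosomes or genes, are reported by sequence, and the planned comparison of small RNA loci was not made. Tags of the moss could thus not be separated from those of other organisms by mapping.

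The 10 files came from 6 biological libraries. Of these, 4 had been sequenced in 2 technical runs, whose counts were summed. They were the libraries of 2009 and of old batch 2, while those of old batch 1 had a single run. Grouping followed the labels: plants of the 2009 collection of the Gransden strain (batch 3), and the older Gransden stock in batch 1 and in batch 2, with 2 libraries per group. The 2009 plants were in 1 batch only, so strain and batch could not be separated. Each comparison with 2009 was therefore also made against each old batch, and a change that passed against both with the same sign is described as repeated. Both comparisons share the 2009 libraries, so a repeated change is not an independent replication.

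Tags of 20 to 24 nt were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr (minimum count of 10, minimum total of 15) left 43348 tags, TMM factors from 0.94 to 1.05 scaled the libraries, and the quasi-likelihood test (glmQLFit and glmQLFTest after estimateDisp) was fitted to all 6 libraries with 1 mean per group. The contrasts were 2009 minus the mean of the old batches, 2009 minus each old batch, and old batch 1 minus old batch 2. The p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05, and the standard error (SE) of a log2 change was its size divided by the square root of the F statistic. The fit took its spread from the libraries within each group. Its p-values and SEs therefore leave out variation between batches, and a call is not evidence on the strain as such. Normalised CPM (counts scaled to the total of 20 to 24 nt reads) are given after TMM for families and tested tags and without TMM for the lists of other organisms, and the errors given with them are SDs over the 2 libraries of a group.

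Counts of microRNA (miRNA) families were sums over tags of 20 to 22 nt that lay within 2 mismatches and an offset of at most 2 nt of a listed sequence. The lists held 16 moss entries in 5 groups, called families here, 17 families of flowering plants and 5 animal miRNAs, written from general knowledge. Of the moss entries, tasiARF belongs to the trans-acting siRNA pathway. The entry miR894 was listed as likely derived from ribosomal RNA and may not be a miRNA. The 13 moss families that passed the filter were tested like the tags, with the TMM factors of the tag table. Counts adjusted over the list alone and over the families and tags together are both given. Families with near-identical sequences, such as miR156, miR529 and miR535, could exchange reads under this matching. Flowering plant and animal lists were counted by exact match only. Shares of each length among the 20 to 24 nt reads were compared by an exact two-sided permutation test over the 15 splits of the 6 libraries. That test treats the libraries as exchangeable and ignores their grouping in batches. Technical runs were compared by a chi-square statistic over tags with a count of 50 or more.

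The family lists, the rule for named tags and the tests were chosen before the data were examined. Named were every listed moss family with a mean of 1 CPM or more, the 5 tags with the largest rise and the 5 with the largest fall among repeated changes with a mean of 10 CPM or more, and the most abundant tag of each length from 20 to 24 nt. A total of 97 tags, 34 higher and 63 lower in 2009, qualified for the naming of rises and falls. Tags named outside this rule are marked as chosen after their values were seen.

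The comparison of 2009 with the old stock was tested on simulated data with the same 43348 tags, in which 200 tags had a known change. Of 50 tags raised by 2 on the log2 scale 86% were recovered, and of 50 lowered by 2 only 28%. For a change of 1 the shares were 8% and 0%. Among 67 calls 6 were false, or 8.96%, above the nominal 5%. Over 10 simulations without any change the highest number of calls was 1. Apart from the set changes, all simulated libraries shared the same mean for each tag, so no difference between batches was simulated. The simulations thus do not show how many calls a difference between batches alone would give.

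Alternatives were DESeq2 1.42.0, its size factors in edgeR, library totals without TMM, no filter beyond a total count of 10, technical run 2 alone, the replicate number as a block, each library left out in turn, exact matching of families, and the most abundant tag of each family. In the setting with technical run 2 alone, the old batch 1 libraries kept their only run. Further alternatives, added after the data had been seen, are named in the closing part. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were made with matplotlib 3.10.9.

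Depth ranged from 10417039 to 19295451 reads per file. Confidence intervals are exact Poisson or binomial intervals at the 95% level and cover counting error only, because reads without molecular identifiers are not independent molecules.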

Results

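The libraries catalogued and quantified the small RNAs of moss protonemata. Those of the 2009 collection held 22622932 and 27764644 reads, those of old batch 1 held 11977882 and 14746066, and those of old batch 2 held 34000721 and 35783199. Reads of 20 to 24 nt, the range of miRNAs and most small interfering RNAs, made up 29.9% to 35.8% of a library, or 3831606 to 12252407 reads. A peak at 21 or 22 nt stood beside a peak of shorter fragments at 16 nt and one of longer fragments at 33 nt. Fragments of 15 to 17 nt made up 26.7% and 25.7% of the reads in old batch 2, 18.8% and 21.8% in 2009, and 17.04% and 14.5% in old batch 1. Fragments of 31 to 42 nt made up 14.6% and 18.8% in old batch 2, 25.7% and 20.6% in 2009, and 30.8% and 35.4% in old batch 1.

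**Figure D1:**
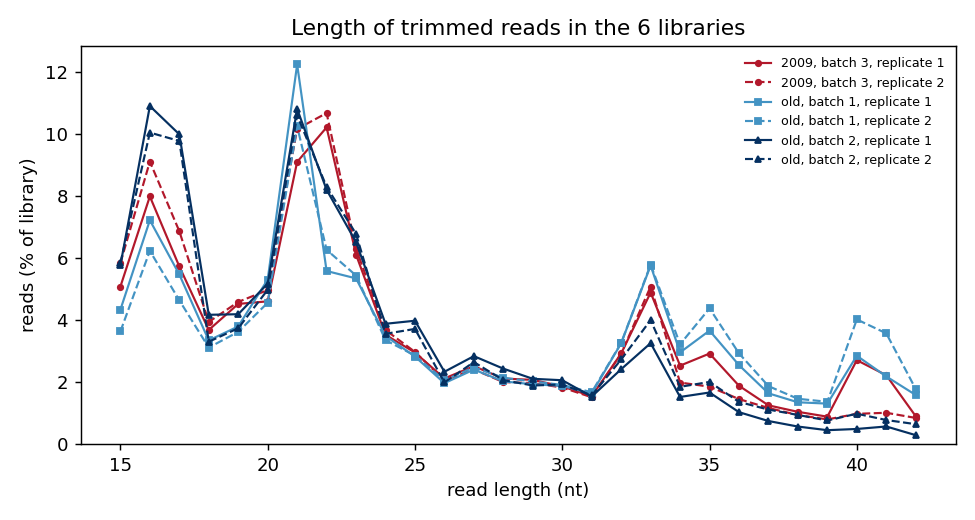
Share of reads (percent of the library) at each read length (nt), with 1 line per biological library, coloured by group, solid for replicate 1 and dashed for replicate 2. Both 2009 libraries lie above all 4 old libraries at 22 nt.

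The technical runs of a library differed by more than counting error alone, but by less than biological replicates. Their chi-square per degree of freedom lay between 2.09 and 2.47 in the 4 libraries with 2 runs, against 9.66 to 19.99 between biological replicates of a group. The correlation of the runs across tags was 0.963 to 0.967. Tags are not independent replicates, so this correlation is a description only.

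Among the listed miRNA families, miR319 was by far the most abundant. This family, which targets transcripts of MYB and TCP transcription factors in land plants, reached 99022 ± 4692 CPM in 2009, 144997 ± 1777 in old batch 1 and 75960 ± 2772 in old batch 2 (SD, n = 2 each). It was followed by miR536 (mean of 10833 CPM over the 6 libraries), miR535 (10243 CPM) and miR166 (8838 CPM), the last known to target HD-ZIP III transcripts. The families miR156, a regulator of SBP transcription factors, and miR390, which triggers trans-acting siRNAs, had means of 2617 and 1139 CPM. The families miR477, miR529, miR160 (a regulator of auxin response factors), miR534 and miR894 lay between 72.8 and 349 CPM, and miR408 and miR171 at 5.72 and 1.08 CPM. Only 2 reads matched miR167, and none matched miR395 or the tasiARF sequence.

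**Figure D2:**
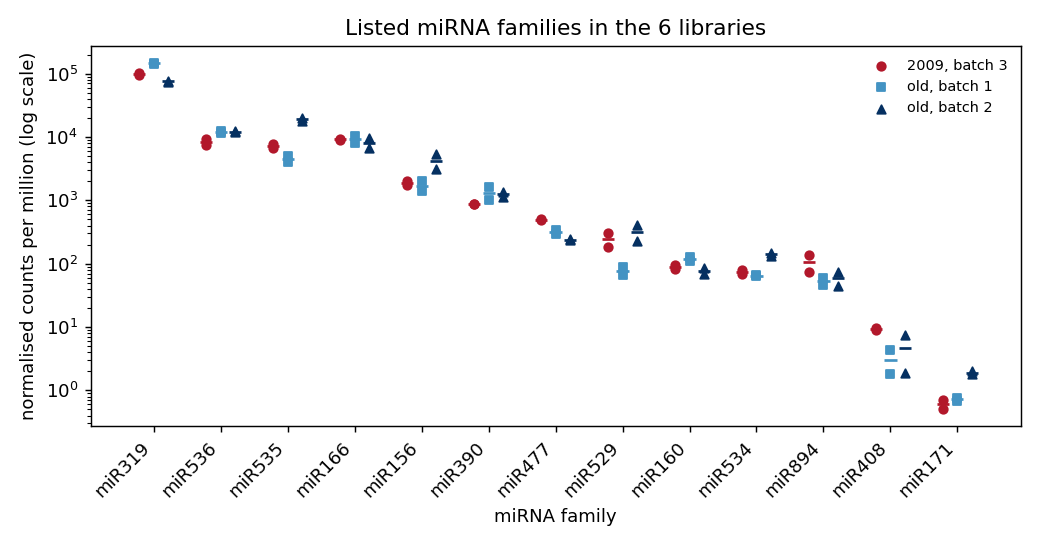
Normalised CPM (log scale) of the 13 tested families, with 1 point per library and a line at the mean of the 2 libraries of a group. Of these, miR894 was listed as likely derived from ribosomal RNA. The miR535 points of old batch 2 lie at 18007 and 19879 CPM, above the other 4 libraries.

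In the comparison of 2009 with the old stock, miR477 was higher in 2009 and no other listed family passed the test. It stood at 492 ± 12.7 CPM in 2009, 317 ± 25.8 in old batch 1 and 239 ± 3.77 in old batch 2, a rise of 0.84 on the log2 scale (SE 0.137, adjusted p = 0.0214 in edgeR), and both 2009 libraries lay above all 4 old ones. This SE and p rest on the spread between libraries within a batch and leave out variation between batches. The rise was repeated, at 2.06-fold against old batch 2 and 1.55-fold against old batch 1, in contrasts that share the 2009 libraries. A repeated fall was seen for miR536, which was 1.42-fold and 1.41-fold lower in 2009 than in old batches 2 and 1, although the contrast with their mean gave an adjusted p of 0.0581. It passed in DESeq2 (0.00372), with the size factors of DESeq2 in edgeR (0.0448) and when fitted together with the tags (0.0359), and miR534 passed as lower in DESeq2 (0.0422). Among the 4 moss-rich families (miR477, miR534, miR535 and miR536) 1 rose, and none of the 6 tested regulators of transcription factors passed. Of these, miR171 and miR529 had log2 changes of -0.965 and 0.66, and miR529 had 0.918 without old batch 2 replicate 2. Changes of families were not simulated, so how often changes of this size are recovered for families is not known. The single tested members of the other groups were miR390, miR408 and miR894, the last listed as likely derived from ribosomal RNA. They had changes of -0.56, 1.31 and 0.91 on the log2 scale and did not pass. Without old batch 2 replicate 2, miR408 (log2 change 1.985, adjusted p = 0.00015) and miR894 (1.124, 0.0228) did, as they did when families were fitted together with the tags (0.0416 and 0.0359).

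The count of 1 family was adjusted over the list alone. Over families and tags together edgeR gave 0 (miR477 adjusted p = 0.0614), with 3 families at an unadjusted p under 0.05, and DESeq2 gave 3 adjusted over the list. Neither repeated call held over families and tags together, since the edgeR adjusted p against old batch 1 was 0.185 for miR477 and 0.209 for miR536. The most abundant miR477 tag, with 42.37% of its reads, had 1 mismatch to the listed sequence, so exact matching left it out. That tag alone rose by 1.061 on the log2 scale (edgeR adjusted p = 0.0163 over the list). The miR477 call was lost with the replicate block (adjusted p = 0.116), with exact matching (0.115), and without 2009 replicate 1 (0.218), 2009 replicate 2 (0.0832), old batch 1 replicate 1 (0.055) or old batch 2 replicate 1 (0.0595), and kept its direction each time. The 2 repeated calls became 0 without TMM, with the replicate block and without any 1 library other than old batch 2 replicate 2, whose removal left 2, both higher in 2009.

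Against single batches, more families differed. Relative to old batch 2, edgeR called 7 of the 13 families (4 over families and tags together). In 2009, miR319 and miR477 were higher, and miR535 (2.62-fold), miR171 (3.16-fold), miR156 (2.25-fold), miR534 (1.87-fold) and miR536 were lower. Relative to old batch 1, 5 families were called (1 over families and tags together). In 2009, miR529 (3.23-fold), miR535 (1.58-fold) and miR477 were higher, and miR319 (1.46-fold) and miR536 lower. The families miR319 and miR535 thus had opposite signs against the 2 old batches. Matches to miRNAs of flowering plants stood at 12.8 and 11.3 CPM (not TMM-scaled) in the libraries of old batch 1 and at most at 0.49 in the other libraries.

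The largest rises among the named tags were those of 2 overlapping tags. Read almost only in 2009 were ATGCAACTTGTATGGACAGAGT, with 880 reads in 2009 and 2 in the 4 old libraries, and TGCAACTTGTATGGACAGAGT, which lacks its first base, with 578 reads against 2. Their ratios, relative to the 20 to 24 nt reads, were 809 (95% interval 223 to 6693) and 532 (147 to 4399). The tag ATGTGATATCACCGAGCCTTG was higher by 3.91 on the log2 scale in 2009 at 45.7 ± 9.12 CPM, against 4.80 ± 0.025 in old batch 1 and 0.486 and 3.34 in the libraries of old batch 2, and by 4.88 without old batch 2 replicate 2. The tag CGGCACACACTCTCTGCCCGG was 10.7-fold higher at 45.4 ± 13.7 CPM, and ACGGTGTCGGGGGTTCGAATCCC was 9.69-fold higher at 53.0 ± 0.19 CPM (SD, n = 2).

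The most abundant tag among the largest falls, TGGCATTGTAGGTTTAAGAGC, dropped to 369 ± 81.7 CPM in 2009 from 2338 ± 90.1 in old batch 1 and 4229 ± 185 in old batch 2. Its fall was 8.52-fold (log2 change -3.09, SE 0.206, adjusted p = 1.75e-05 in edgeR). The overlapping tags TCTTAGATCTACAATGCCTC and TCTTAGATCTACAATGCCTCT were 15.3-fold and 13.4-fold lower. The tag AGTCTCCATGCTTCTCTGACG was 7.82-fold lower, at 37.9 ± 9.30 CPM against 180 ± 52.7 and 491 ± 111. The tag GGGATTGTAGTTCAATTGGTTACT was 7.51-fold lower, with old batch 1 at 73.4 ± 9.05 CPM and old batch 2 at 28.1 ± 24.9, and its adjusted p rose from 0.015 to 0.0744 without 2009 replicate 1. These 10 tags were selected as the largest repeated changes, so their sizes are at the upper end by construction.

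**Figure D3:**
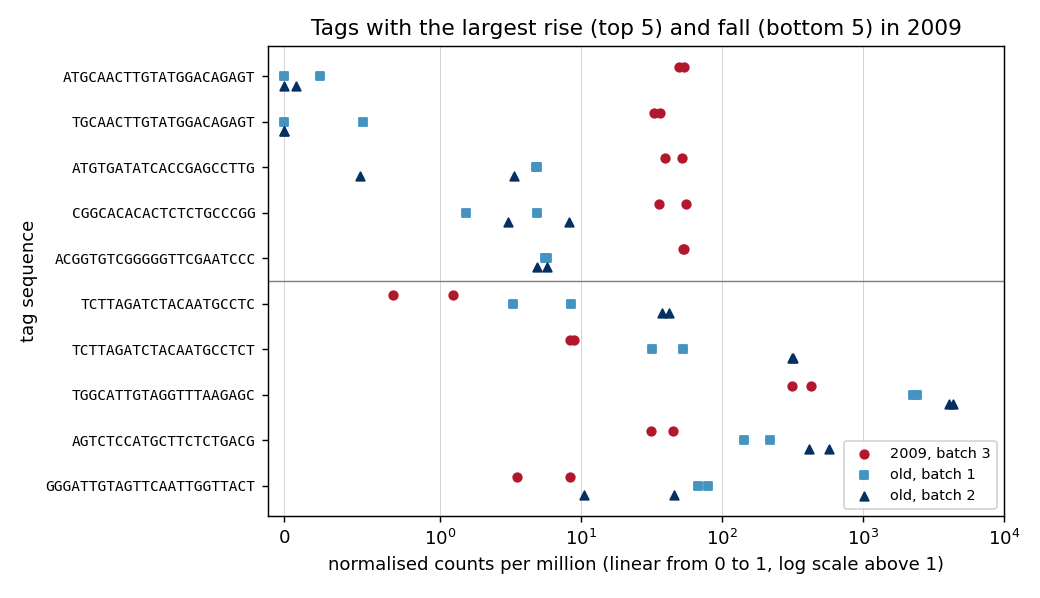
Normalised CPM (linear from 0 to 1, log scale above) of the 5 tags with the largest rise and the 5 with the largest fall in 2009, with 1 point per library coloured by group. The 2009 points of TGGCATTGTAGGTTTAAGAGC lie at 311 and 427 CPM, and those of old batch 2 at 4360 and 4098.

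Of the 43348 tags tested, 953 differed between 2009 and the old stock, 610 higher and 343 lower (64.0% higher), and 875 of these by at least 2-fold. The split depended on the tool, with 398 higher and 380 lower of 778 in DESeq2, and on the batches used. It was 143 higher and 166 lower without the libraries of old batch 2, and 980 and 878 without those of old batch 1. In simulated data rises were recovered more often than falls. Repeated changes against both old batches numbered 181, with 87 higher and 94 lower, and the split depended on the setting (66 and 108 without TMM, 20 and 42 with the replicate block, 196 and 117 without the filter). Independent lists of the same sizes would share 7.8 and 5.7 tags, and 6 tags changed in opposite directions. The covariance of the log2 changes against the 2 old batches was 0.285 against 0.166 in 10 simulations of unchanged groups that shared the 2009 libraries, and their correlation was 0.27 against 0.45. The covariance thus lay above the simulated value and the correlation below it, so these 2 measures do not settle whether there is an excess beyond the shared libraries. The 2009 group has 2 libraries and could not be split. Part of the excess of repeated tags over independent lists may therefore come from the shared libraries. The simulations also held no difference between batches.

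Leaving out 1 library moved the 953 calls to 209 (without 2009 replicate 1), 429 (old batch 1 replicate 1), 609 (old batch 1 replicate 2), 1486 (old batch 2 replicate 1) or 2097 (old batch 2 replicate 2), and the replicate block to 510. In the same order the 181 repeated changes became 47, 25, 43, 352, 460 and 62. Against old batch 1 alone 422 tags were called and against old batch 2 alone 2771, and since 2009 was 1 batch, strain and batch cannot be told apart in any of these counts.

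The batches of the old stock, which share a strain label, differed from each other in 3264 tags, against 2771 between 2009 and old batch 2 and 422 between 2009 and old batch 1. The order of the first 2 counts turned in 3 of the 6 fits with 1 library left out (1030 against 2654 without old batch 1 replicate 1, 470 against 2185 without its replicate 2, and 3526 against 3654 without old batch 2 replicate 2). Relative to old batch 2, old batch 1 had 1.91-fold more miR319 and less of 5 other families. It had 4.15-fold less miR535 (4566 ± 725 against 18943 ± 1323 CPM, SD, n = 2), 4.19-fold less miR529, 2.61-fold less miR171, 2.48-fold less miR156 and 2.16-fold less miR534, the last known in this moss to target transcripts of BOP genes. The miR171 difference rested on 3 and 3 reads in old batch 1 and 25 and 22 in old batch 2, and 63.49% of the reads of this family were 1 tag with 2 mismatches to the listed sequence. The most abundant miR529 tag, with 73.01% of its reads, had 2 mismatches as well, and with exact matching the log2 change of miR529 was -3.50 in place of -2.07. By group, 4 of the 6 tested regulators of transcription factors and 2 of the 4 moss-rich families passed, and miR390, miR408 and miR894 did not, although miR408 passed without old batch 2 replicate 1 (adjusted p = 0.00871). Beside these differences, old batch 1 held fewer reads of 15 to 17 nt (17.04% and 14.5%, against 26.7% and 25.7%) and more of 31 to 42 nt (30.8% and 35.4%, against 14.6% and 18.8%). The 2009 libraries lay between the old batches in both classes, as they did for miR319 and miR535. Of the 5 named falling tags 4 also differed here. TCTTAGATCTACAATGCCTCT was 7.45-fold, TCTTAGATCTACAATGCCTC 6.66-fold, AGTCTCCATGCTTCTCTGACG 2.73-fold and TGGCATTGTAGGTTTAAGAGC 1.81-fold lower in old batch 1, while GGGATTGTAGTTCAATTGGTTACT was 2.61-fold higher there and did not pass (adjusted p = 0.121), except without old batch 2 replicate 2 (2.2e-05) or 2009 replicate 2 (0.0342).

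In edgeR, 6 of the 13 families passed over the list alone and 3 (miR319, miR534 and miR535) over families and tags together. Their adjusted p over the list ran from 0.000299 for miR319 to 0.024 for miR156 and miR171. Among tags 3264 differed, with 1682 higher and 1582 lower in old batch 1 (1569 and 2440 without the filter, 1358 and 1727 without old batch 2 replicate 1, 1371 and 2155 without its replicate 2), and matches to flowering plant miRNAs were at 12.8 and 11.3 CPM in its libraries. Without old batch 1 replicate 1 the counts were 1030 tags and 3 families, and without its replicate 2 they were 470 tags and 3 families, where miR156, miR171 and miR529 no longer passed. The call of TGGCATTGTAGGTTTAAGAGC was lost without either of them (adjusted p = 0.0703 and 0.114), and that of AGTCTCCATGCTTCTCTGACG without replicate 2 (0.0942). With exact matching 4 families were called, and miR171 and miR534 had too few reads to be tested, as had miR171 for its most abundant tag and with technical run 2 alone. Whether a library of old batch 1 was made with an earlier kit is not settled by the labels, so a difference of kit stays open here. DESeq2 gave 2018 tags and 7 families, 3 higher and 4 lower in old batch 1. It did not call miR171 (adjusted p = 0.0627) and added miR160 (log2 change 0.606, adjusted p = 0.00643) and miR477 (0.418, 0.00149) as higher. With the replicate block miR156 (0.0662) and TGGCATTGTAGGTTTAAGAGC (0.0546) no longer passed.

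Reads of 22 nt took a larger share of the 20 to 24 nt reads in 2009. The share was 30.1% ± 0.43 (SD, n = 2) in 2009 and 21.6% ± 3.11 in the old stock (n = 4), where old batch 1 held 19.2% ± 2.49 and old batch 2 held 23.98% ± 0.37. The 21 nt share was 27.8% ± 0.90 in 2009 and 33.7% ± 3.41 in the old stock. A single tag, TCAAACGAATAAGGGCTTATGG, made up 16.8% ± 0.26 of the 20 to 24 nt reads in 2009 and 8.01% ± 3.00 in the old stock. Without it the 22 nt shares were 16.1% and 14.8%, a difference of 1.28 percentage points. The 20, 23 and 24 nt shares differed by -1.54, -0.48 and -0.55 points. All shares are parts of the same total, so a higher share of this 22 nt tag lowers those of other lengths. Without the tag, the 20 nt difference was -0.091 points in place of -1.54, and the 21 nt difference -3.24 in place of -5.95. The tag matched none of the listed families, and whether it is a fragment of a longer RNA was not determined.

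The difference of 8.53 points at 22 nt had an exact two-sided permutation p of 0.0667, the smallest that 15 splits allow, and 0.222 after adjustment over the 5 lengths. With 2 libraries against 4 this permutation test cannot reach 0.05. It also treats the libraries as exchangeable, although they were grouped in batches. Old batch 1 minus old batch 2 was -4.76 points at 22 nt, so its p overstates the evidence where batches differ. The 22 nt difference was 10.9 points against old batch 1 and 6.15 against old batch 2.

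The most abundant tags of each length included 2 of the miR319 family. CTTGGACTGAAGGGAGCTCCC (21 nt) stood at 81985 ± 3047 CPM in 2009, 109096 ± 3673 in old batch 1 and 54232 ± 2763 in old batch 2. CTTGGACTGAAGGGAGCTCC (20 nt) was 1.76-fold lower in 2009 than in the old stock (adjusted p = 0.0163 in edgeR). At 22 nt, TCAAACGAATAAGGGCTTATGG was 2.30-fold higher in 2009 (adjusted p = 0.00995), at 174101 ± 8484 CPM against 57018 ± 24762 and 100533 ± 12669. The tag CTAACAGACCGAGAGATTTGAAC (23 nt) had a log2 change of 0.06, and CCTAACAGACCGAGAGATTTGAAC (24 nt), with 1 more base at its 5′ end, was 1.79-fold higher (adjusted p = 0.0341). None of these 5 passed against both old batches with the same sign. Those of 22, 23 and 24 nt matched none of the listed families, and whether they are fragments of longer RNAs was not determined. Without 2009 replicate 1, the calls of CTTGGACTGAAGGGAGCTCC and CCTAACAGACCGAGAGATTTGAAC were lost (adjusted p = 0.204 and 0.314), as they were with the replicate block (0.0573 and 0.0891). The second call was also lost in DESeq2 (0.0564).

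Lists of miRNAs not expected in moss were counted as a check for RNA or reads of other organisms. The 17 flowering plant families gave 49 and 50 reads in the libraries of old batch 1, or 12.8 (95% interval 9.46 to 16.9) and 11.3 (8.42 to 14.96) CPM. The other 4 libraries had 1 to 6 reads. In old batch 1, miR158 had 69 reads and miR159 25, against 0 and 9 in the other 4 libraries together. With a floor of 3 counts over those 4 libraries, miR158 was at least 116-fold higher in old batch 1. The 5 animal miRNAs had 1 read in all libraries together.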

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

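The tests in this part were chosen after the counts of the flowering plant list had been seen. That list is outside the comparisons of moss small RNAs, and its level in the libraries of old batch 1, at 12.8 and 11.3 CPM, lay above the level in the other libraries and above what a count of 0 allows. If miR158 were a sequence of the moss itself, old batch 2, with the same strain label, would have held 201.1 reads at the old batch 1 rate, and it held 0. Reads or RNA of a flowering plant in old batch 1 may therefore be the source, as carry-over from another library or as plant material, and these were not separated. Of the 17 listed families, 2 (miR158 and miR159) had 3 or more reads in old batch 1 and at most 3 in every other library, which is too few to set against a profile of such a plant, and 11 families had 0 reads throughout.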

How the results depend on the processing

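The settings that were added after the data had been seen are the fits without the libraries of 1 old batch, without the 3 most abundant tags, at equal depth and of families together with tags, the ratio of calls between comparisons with 1 library left out, and the shares without the most abundant 22 nt tag. The cause of a change between settings was not tested unless stated. For tags of 2009 against the old stock (953), the count was 1562 (1145 higher) without the filter, where more tags were tested, 1858 without the libraries of old batch 1 and 309 without those of old batch 2, and 209 to 2097 when 1 library was left out. For old batch 1 against old batch 2 (3264) it was 2018 in DESeq2 and 470 to 4010 with 1 library left out. For repeated changes (181) it was 313 without the filter and 25 to 460 with 1 library left out. A group left with 1 library was assumed to vary like the others. Other scalings, technical run 2 alone, equal depth and removal of the 3 most abundant tags kept all 3 counts within 1.5 times.

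For families of 2009 against the old stock (1), the count was 3 in DESeq2, 2 with its size factors in edgeR, 0 with exact matching, 4 when fitted together with the tags, 5 without the libraries of old batch 1, 6 without those of old batch 2, and 0 to 4 with 1 library left out. For old batch 1 against old batch 2 (6) it was 3 to 7 with 1 library left out. For families repeated against both old batches (2) it was 0 without TMM, 1 with technical run 2 alone, 1 with exact matching, and 0 to 2 with 1 library left out.

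The differences between replicates 1 and 2 correlated across tags at -0.20 (2009 and old batch 1), 0.29 (2009 and old batch 2) and -0.36 (the old batches). They thus gave no sign of a pairing by replicate number common to all groups. With a single difference per group, a pairing of 2009 with old batch 2 is not excluded. With the replicate block, 510 tags, 2273 tags between the old batches, 62 repeated tags, 0 families, 5 families between the old batches and 0 repeated families were called.

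Among length shares, counting distinct tags in place of reads turned the 20 nt difference to 0.79 points and the 21 nt difference to 0.32, and removal of the most abundant 22 nt tag turned those at 23 and 24 nt to 1.47 and 0.58. The 22 nt difference kept its sign throughout, and was 0.505 points when distinct tags were counted. Over the reads of 18 to 30 nt, a larger total, the differences at 20, 21 and 22 nt were -0.80, -3.32 and 5.45 points. In the main setting they were -1.54, -5.95 and 8.53. Of 382 alternative values of single families 12 changed sign, 13 gained and 16 lost significance, and of 414 of single named tags 8, 9 and 17 did. The families miR171 and miR534 had no value with exact matching, and miR171 had none for its most abundant tag or with technical run 2 alone, since they did not pass the filter there. Values that changed sign belonged to families or tags that had not passed. For 2009 against the old stock, miR166 had a log2 change of -0.06 for its most abundant tag and -0.035 with exact matching, miR319 had 0.092 for its most abundant tag, and CTAACAGACCGAGAGATTTGAAC had -0.023 without TMM. With 1 library left out, miR160 ran from -0.175 to 0.025, miR166 from -0.012 to 0.23, miR319 from -0.10 to 0.01 and CTAACAGACCGAGAGATTTGAAC from -0.047 to 0.24. Between the old batches, miR166 ran from -0.11 to 0.41, miR390 from -0.34 to 0.33, miR408 from -1.38 to 0.67, miR894 from -0.55 to 0.24, ATGCAACTTGTATGGACAGAGT from -1.98 to 3.02 and CGGCACACACTCTCTGCCCGG from -1.94 to 0.071. There ACGGTGTCGGGGGTTCGAATCCC ran from -0.071 to 0.19, and had -0.05 without the filter. Some called changes kept their sign but moved in size. For 2009 against the old stock, CGGCACACACTCTCTGCCCGG had a log2 change of 4.01 without old batch 1 replicate 2, against 3.42, and GGGATTGTAGTTCAATTGGTTACT had -3.65 without 2009 replicate 2 and -2.19 without old batch 2 replicate 2, against -2.91. Between the old batches, TCTTAGATCTACAATGCCTC had -3.66 without old batch 1 replicate 2, against -2.74. The alternatives planned for small RNA loci were not run, because no genome was used here. Depth limited the old batch 1 libraries most, with 3831606 and 4407538 reads of 20 to 24 nt.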

Other observations

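All tests in this part were chosen after the results they bear on had been seen, as were tags named only here. Some single sequences outside 20 to 24 nt were abundant. The 33 nt fragment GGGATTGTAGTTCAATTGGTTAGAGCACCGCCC stood at 12379 to 24171 CPM over reads of all lengths, and its first 22 bases are those of GGGATTGTAGTTCAATTGGTTACT, a tag that fell in 2009. The 16 and 17 nt fragments GCCCCCATCGTCTAGT and GCCCCCATCGTCTAGTG were highest in old batch 2, at 56473 and 52545, and at 57471 and 60732 CPM, against at most 34152 and 25974 in the other libraries. Tags that share the last 18 bases of CTAACAGACCGAGAGATTTGAAC formed a ladder of 199 sequences with 10.7% to 16.1% of the 20 to 24 nt reads of a library. Among 22 nt reads 77.3% ± 0.58 in 2009 began with T, against 63.0% ± 5.03 in old batch 1 and 68.8% ± 2.79 in old batch 2 (SD, n = 2; exact permutation p = 0.067, 0.267 adjusted over 20 shares), and more than 55% of the 22 nt reads of the 2009 libraries were the single tag TCAAACGAATAAGGGCTTATGG.

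Several tags that fell in 2009 may be strands of one duplex, as miRNA precursors release them. With 2 nt left free at each 3′ end, TGGCATTGTAGGTTTAAGAGC and TCTTAGATCTACAATGCCTCT formed 18 base pairs (G with T included) over 19 facing positions, and among 4724 other abundant tags 1 paired as well or better. That tag, TCTTAGATCTACAATGCCACC, formed 19 pairs over 19 positions and was 3.60-fold lower in 2009, at 428 ± 145 CPM against 972 ± 39.2 in old batch 1 and 2450 ± 145 in old batch 2 (edgeR adjusted p = 0.00138). The best partner of the reversed sequence formed 14 pairs over 18 positions. The miR319 tag CTTGGACTGAAGGGAGCTCCC, treated alike, formed 18 pairs over 19 with GAGCTTTCTTCGGTCCAATAG. Without a genome, a shared precursor could not be looked for.

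A pair of overlapping tags was read almost only in 2009. At the 2009 level 1618 reads of ATGCAACTTGTATGGACAGAGT would have stood in the old libraries, which held 2. The abundant related tag ATGCAACTTGTGTGGACAGACT differs from it by G12A and C21G (bases of the related tag first, positions from the 5′ end). Sequencing errors of the related tag are argued against as the source, since the related tag was not higher in 2009. It stood at 3884.1 CPM in 2009, 3990.3 in old batch 1 and 6268.5 in old batch 2 (not TMM-scaled). The lowest ratio of the pair in a 2009 library was 234.1 times the highest in an old one. A large value was built in here, because the tag was chosen as almost only in 2009. The count of unrelated tags almost only in 2009 was 0, but old batch 1, which held reads of flowering plant miRNAs, had only 1 tag of this kind. RNA or reads of another organism in the 2009 libraries therefore stay open. A difference between the strains rather than between the batches may be the cause, but with 1 batch of 2009 plants these cannot be told apart. Its best partner in a duplex was TATGTCCATTGCAGTTGCATAC, a member of the miR534 family, with 16 pairs over 20 positions, against 15 over 18 for the reversed sequence. Net of mismatches both had 12, so the partner was no better than this control on that score. The score counts G with T as a pair and ignores where mismatches fall. It therefore does not decide whether the 2 tags are strands of one duplex.

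Old batch 1 was nearer to 2009 than to old batch 2. Across 5821 tags, which are not independent replicates, its libraries correlated with those of 2009 at 0.883 to 0.910 and with those of old batch 2 at 0.818 to 0.845, and 7.73 times as many tags differed between the old batches as between 2009 and old batch 1. That ratio was 23.4 without old batch 1 replicate 1, 4.61 without its replicate 2, and 2.33 and 2.31 without replicates 1 and 2 of old batch 2. Sequenced depth alone is argued against by a ratio of 5.56 at equal depth, and size selection of the libraries by a ratio of 4.41 among 21 nt tags. Whether the pattern holds for miRNAs or rests on fragments of abundant RNAs cannot be told apart, as the root mean square log2 change of the 13 families was 1.08 between the old batches and 0.81 between 2009 and old batch 1 (exact sign-flip p = 0.246). The sign-flip test treats families as independent, although some can exchange reads and both changes share the old batch 1 libraries. Its p does not measure variation between libraries. A difference of library kit, which the labels leave open for old batch 1, was not tested as a cause. A biological difference between the strains stays untested, and it would not by itself place an old batch nearer to 2009 than to the other old batch.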
